A study of Mus musculus and Homo sapiens with 6 samples.

How the data were processed

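ATAC-seq libraries of NMuMG cells, a mouse mammary gland epithelial line, were made from 25000, 50000, 75000 and 100000 cells. Per the labels' protocols, cells were lysed in a detergent buffer containing sucrose, their nuclei were incubated with the Tn5 enzyme, and the resulting DNA was purified and amplified by PCR. There were 4 libraries, 1 per cell number, grouped by the cell number in their titles. A further 2 samples of the human line MDA-MB-231 were not analysed here.

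Per the submitters' processing notes, the tools used were cutadapt, Bowtie 0.12.8, SAMtools, Picard 1.107 and bedtools 2.17.0, with the genome builds mm10 and hg19; mm10 was taken for the mouse libraries. The role of each tool, the settings of the peak caller, any shift of reads for the Tn5 insertion and any thinning of reads to a common depth are not given in the sources used here. The authors deposited 1 list of peaks per library, called on that library alone as far as the lists show, with a position and a whole-number score per peak; what the deposited score is computed from is not given. The score is the authors' own value of each peak and was used only to describe, rank and filter peaks within a list. The lists hold only peaks with a score of 8 or above, so that a region without a peak may have signal below that level. No read counts come with the lists. Depth is therefore unknown, and a list may be longer because its library was sequenced more deeply or because more regions passed the threshold.

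Some peaks of a list overlapped others of the same list, and merging them lowered the number of peaks by between 6.45% and 7.37%; peaks were counted as deposited, and covered lengths were taken after merging. A peak was counted as found in another library when it overlapped a peak of that library by at least 1 bp. Shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only and not the spread between libraries. The same shares were computed for 20 sets of peaks shuffled within their chromosomes. All lists were then merged where they overlapped, and each merged region was counted by the libraries with a peak in it.

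Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 49980 genes placed on chromosomes, 21900 of them protein-coding. The table gives the start and end of each gene but no strand, so the plan to use transcription starts was replaced by using both annotated ends, and exons and introns were not separated. A peak was assigned to a gene end when its centre was within 1 kb of one, otherwise to a gene body or to intergenic sequence. A gene was counted as having a gene-end peak when a peak overlapped the 1 kb to either side of either end. The outer ends come from the longest annotated extent of a gene, so that a start inside it is missed, and the window of a gene can hold the end of a neighbour.

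Before the data were examined, 17 gene lists with 295 different genes were fixed, and all of these genes were matched by symbol. They cover housekeeping, epithelial, mammary luminal, mammary basal, epithelial-mesenchymal transition, TGF-beta signalling, AP-1 and immediate early, Hippo pathway, cell cycle, chromatin regulator and stress response genes, and markers of fibroblasts, blood cells, endothelium, neurons, liver and muscle, and pluripotent cells. The number of genes of a list with a gene-end peak is described by its percentile among 10000 random lists of as many protein-coding genes, with ties counted at their midpoint; this describes these libraries and is not a test. The random lists were not matched on base composition, since no genome sequence was used. Genes were named by a rule fixed beforehand: in each list, up to 4 genes with a peak in all 4 libraries and the highest mean score percentile, up to 3 with no peak in any library and up to 4 with a peak in some libraries, both in list order. Regions named were the 5 found in all 4 libraries with the highest mean score percentile and the 2 highest-scoring peaks of each library without overlap in the other 3. Some items these rules select are not reported here.

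Alternatives were a reciprocal overlap of 50%, peaks resized to 200 bp, the peaks at or above each list's median score, equal numbers of highest-scoring peaks, autosomes only, other windows around gene ends, protein-coding genes only and leaving out each library. Those added after seeing the data were merging overlapping peaks of a list, leaving out 61 to 64 Mb of chromosome 15, using gene ends for starts, and counting peaks anywhere in a gene or within 1 kb of it. A planned count of 16 motifs in peaks needs the genome sequence and was not run. The overlap functions were run on constructed data. For 41330 intervals, each kept as an exact copy or moved far away, the known share was recovered with a difference of 0 percentage points. The same held for 200 peaks planted at gene ends and 200 planted between genes. These cases hold no partial overlap and no peak near the edge of a window, so they check the functions in plain cases only. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.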

Results

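Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in NMuMG cells, an epithelial line derived from mouse mammary gland. Libraries were made from 25000, 50000, 75000 and 100000 cells, with 1 library at each cell number, so that no value has a replicate error and no test between cell numbers was made. The series was set up to tune the ATAC-seq protocol, and the comparison addressed here is how the list of open regions and the genes beside them differ with the number of cells put in. The series also has 2 samples of the human breast cancer line MDA-MB-231, which were not analysed here. Each NMuMG library is represented by a list of peaks with a score given by the authors' peak caller. The lists carry no read counts, so the sequencing depth behind each of them is unknown.

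The regions with the highest scores in all 4 libraries lay on the mitochondrial chromosome, and many high-scoring regions outside it lay around the Myc proto-oncogene on chromosome 15. The list from 25000 cells held 38878 peaks covering 21.0 Mb, that from 50000 cells 43832 peaks covering 24.4 Mb, that from 75000 cells 41509 peaks covering 23.0 Mb, and that from 100000 cells 45530 peaks covering 25.7 Mb. The longest list thus had 1.17 times as many peaks as the shortest, and the 75000-cell list was shorter than the 50000-cell list. With 1 library per cell number, these differences cannot be set against the spread between libraries made from the same number of cells. The median peak width was 550 bp in each list. The lowest score was 8 in every list, and the median score was 15, 16, 15 and 16 from the smallest to the largest cell number.

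The 5 regions with the highest score ranks in all 4 libraries were on the mitochondrial chromosome, whose DNA carries no nucleosomes. They lay, in mm10 coordinates, at 10751 to 11850 over ND4, 14051 to 16299 over CYTB, 11851 to 13250 over ND5, 5551 to 6600 over COX1 and 1701 to 4750 over ND1, all genes of the respiratory chain. The ND4 region had the highest score of each list, at 9056, 12219, 15492 and 16091 from 25000 to 100000 cells. These scores rank peaks within a list and were not compared between lists. The mitochondrial chromosome held 6, 7, 8 and 10 peaks. Outside it, the highest score of each list belonged to a peak on chromosome 1 at 24612301 to 24613100, over the pseudogene Gm10222, with scores of 2156, 3254, 4674 and 4149. It was followed by a region on chromosome 2 at 98666351 to 98667450, outside annotated genes, with scores of 1510, 1365, 1674 and 1606. Both scored above every region around Myc in each list. No regions were filtered out of the lists here, and whether repeated sequence or misplaced reads raise these scores was not tested. These regions and the others named outside the mitochondrial chromosome were chosen after their values were seen.

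Chromosome 15 between 61 and 64 Mb contained the 1 Mb window with the most peaks in the genome, on average over the 4 libraries. The 1 Mb window that starts at 62 Mb, which contains the long non-coding RNA gene Pvt1 and starts just beyond Myc, contained 180, 188, 166 and 155 peaks from the smallest to the largest cell number. The median 1 Mb window of the genome contained 10 to 13. Over the 3 Mb as a whole there were 372, 362, 330 and 309 peaks, or 124, 121, 110 and 103 per Mb. Of the 100 highest-scoring peaks outside the mitochondrial chromosome, 24, 24, 22 and 25 were in this block. They included a region at 62328101 to 62329350, beyond the annotated end of Pvt1, with scores of 618, 832, 839 and 911, and a region at 62079001 to 62080050 inside Pvt1, with scores of 534, 583, 531 and 613. The peak at the lower annotated end of Myc, at 61984751 to 61985850 in the 100000-cell library, scored 186, 251, 235 and 297. The number of copies of this block in the cells was not measured.

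**Figure D1:**
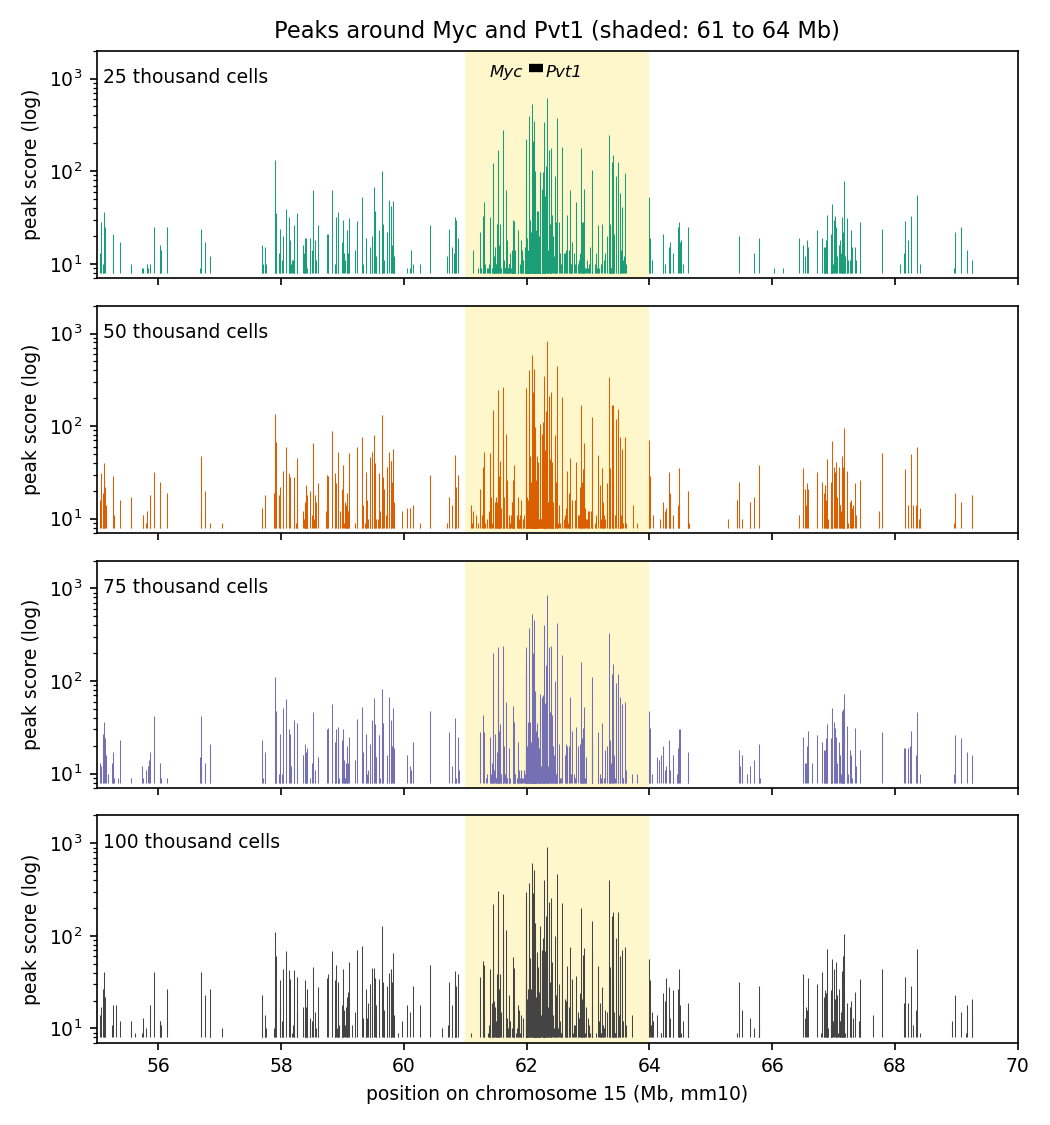
Peaks on chromosome 15 from 55 to 70 Mb (mm10), 1 panel per NMuMG library; each vertical line is a peak at its centre, drawn up to the authors' score on a log axis. The shaded 61 to 64 Mb, with Myc and Pvt1 marked in the top panel, holds 372, 362, 330 and 309 peaks from 25000 to 100000 cells.

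Genes and regions with high scores were found at each cell number, and the lists differed mainly in their low-scoring peaks. The epithelial genes Jup and Elf3, named by rule for high-scoring peaks in all 4 libraries, had them at the same end each time. When all 4 lists were merged into 55702 regions, 25787 of them (46.3%, 95% Clopper-Pearson interval 45.9 to 46.7) had a peak in all 4 libraries and 14607 (26.2%, 25.9 to 26.6) in a single library. The intervals here and below cover counting error only. Regions found in all 4 libraries had their centre within 1 kb of an annotated gene end in 37.9% of cases, compared with 13.1% for regions of a single library. This comparison was not made at equal score.

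Taken from each list, 72.5% (72.1 to 73.0) of the peaks at 25000 cells, 63.7% (63.2 to 64.1) at 50000 cells, 67.5% (67 to 67.9) at 75000 cells and 61.2% (60.8 to 61.7) at 100000 cells overlapped a peak in all 3 other libraries. Peaks shuffled within their chromosomes did so in 1.33% to 1.39% of cases. The order of these shares is the reverse of the order of list lengths, and with the same number of highest-scoring peaks from each list they lay between 66.2% and 68.8%. Between pairs of libraries, 72.4% to 85.5% of the peaks of a list overlapped a peak of the other list. Peaks that overlapped none in the other 3 libraries numbered 2614 (6.72%, 6.48 to 6.98) at 25000 cells, 4338 (9.90%, 9.62 to 10.2) at 50000 cells, 3387 (8.16%, 7.90 to 8.43) at 75000 cells and 5031 (11.0%, 10.8 to 11.3) at 100000 cells.

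**Figure D2:**
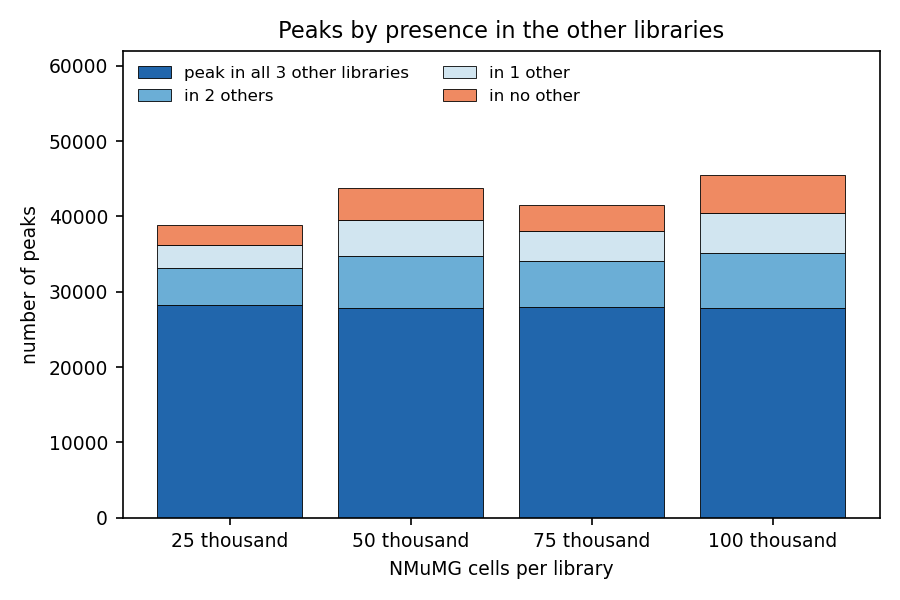
Number of peaks in each NMuMG library, stacked by how many of the other libraries have an overlapping peak. The peaks found in all 3 other libraries number between 27883 and 28200, while those found in no other library range from 2614 to 5031.

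Sharing followed the score within each list. Among peaks with a score of 8 or 9, 38.1% (37.0 to 39.1) at 25000 cells, 23.1% (22.2 to 24) at 50000 cells, 29.7% (28.7 to 30.6) at 75000 cells and 20.8% (19.9 to 21.6) at 100000 cells were found in all 3 other libraries. The order of these shares is again the reverse of the order of list lengths, so the cell numbers were not compared by them. At scores from 25 to 49 the shares were 99.5%, 98.4%, 99% and 97.8%. At scores of 50 and above they were 100% in 3 libraries, and at 75000 cells 3466 of 3467 peaks were shared. Peaks of a single library had a median score of 9 in each list, and the highest score among them was 25, 28, 21 and 25.

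**Figure D3:**
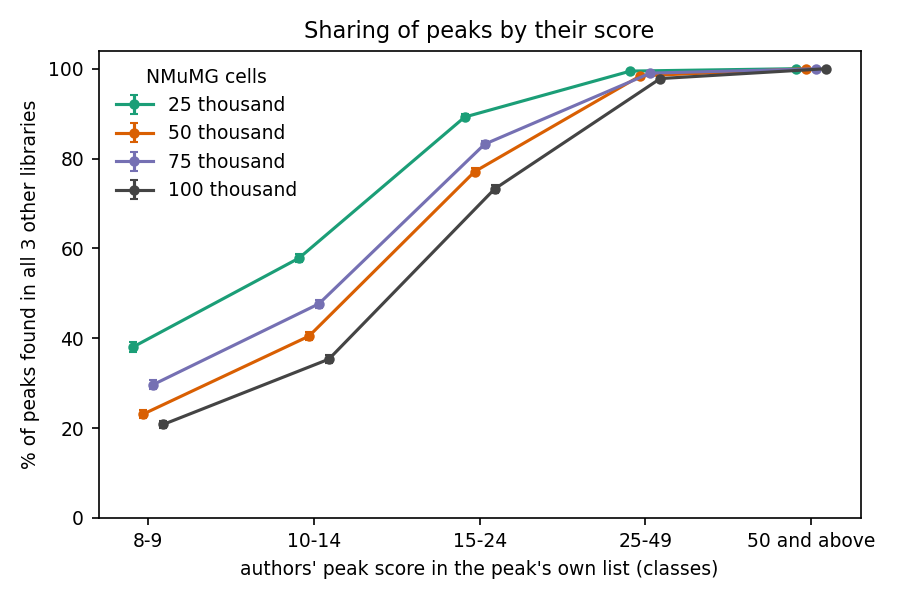
Share of peaks found in all 3 other libraries (%) by class of the authors' score within the peak's own list, for each NMuMG library; bars are 95% Clopper-Pearson intervals, mostly smaller than the points. The share is lowest at scores of 8 and 9 (20.8% to 38.1%) and close to 100% from a score of 25.

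Among the peaks found in a single library, the 2 with the highest scores were located for each cell number. At 25000 cells they were at 70777901 to 70778500 on chromosome 14, at the upper end of Dok2, an adaptor protein gene, with a score of 25, and at 46471301 to 46471900 on chromosome 8 in Acsl1, which encodes an acyl-CoA synthetase, with a score of 22. At 50000 cells they were at 31399101 to 31399700 on chromosome 16, outside annotated genes, with a score of 28, and at 71591001 to 71591550 on chromosome 6 in the histone demethylase gene Kdm3a, with a score of 23. At 75000 cells both scored 21, at 156616851 to 156617350 on chromosome 1 in the tyrosine kinase gene Abl2 and at 72249901 to 72250500 on chromosome 6 in the non-coding gene Gm30782. At 100000 cells they were at 19901851 to 19902450 on chromosome 13, outside annotated genes with Gpr141 as the nearest, with a score of 25, and at 5841901 to 5842450 on chromosome 19 in the non-coding RNA gene Neat1, with a score of 24. Neither their presence in 1 list nor their absence from the others has a replicate check.

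Peaks were concentrated at gene ends at every cell number. The gene table used gives no strand, so that the transcription start could not be told from the end of the gene, and both annotated ends were used in place of promoters. Of the peaks, 33.4% (32.9 to 33.9) at 25000 cells, 31.5% (31.0 to 31.9) at 50000 cells, 32.6% (32.2 to 33.1) at 75000 cells and 31.5% (31.1 to 31.9) at 100000 cells had their centre within 1 kb of a gene end. These shares are 5.15, 4.88, 5.05 and 4.87 times those of shuffled peaks. A further 41.2% to 41.9% lay elsewhere inside genes, and 25.4% to 26.7% lay between genes, where 48.6% to 48.8% of shuffled peaks fell. Peaks at gene ends were found in all 3 other libraries more often than intergenic peaks in each list, with 86.3% against 64.3% at 25000 cells, 79.8% against 54.3% at 50000 cells, 81.9% against 58.6% at 75000 cells and 76.9% against 52.0% at 100000 cells. Peaks at gene ends also had higher scores, with medians of 19, 23, 21 and 23 against 13, 14, 13 and 14 for intergenic peaks. The shares were not compared at equal score.

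Of 21900 protein-coding genes, 9613 (43.9%) had a peak overlapping the 1 kb around one of their ends in all 4 libraries and 10364 (47.3%) in none. Genes with such a peak in some libraries were fewer, with 768 in 3 libraries, 505 in 2 and 650 in 1. Per library the number was 10267, 10711, 10593 and 10845 from 25000 to 100000 cells. In each library 88.3% to 89.5% of these genes had a peak at 1 end only. A gene without a peak here is one without a listed peak at either outer end, and it may carry a listed peak at an internal start.

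Epithelial genes carried peaks in part. Of 30 genes for cell junctions, keratins and epithelial regulators, 14 had a peak at a gene end in all 4 libraries, at the 62.2 percentile of 10000 random lists of 30 protein-coding genes. Jup, which encodes the junction protein plakoglobin, had a peak at its upper end on chromosome 11, at 100397401 to 100398250 in the 25000-cell library, with scores of 84, 101, 105 and 91 from the smallest to the largest cell number. The epithelial transcription factor gene Elf3 scored 79, 78, 85 and 84 on chromosome 1, and the window of the tight junction gene Tjp3 held peaks of 72, 87, 66 and 85 that lay beyond the gene and nearer to the end of its neighbour Pip5k1c. Cdh1, the E-cadherin gene, and Krt8, a simple epithelial keratin gene, were chosen after their values were seen and had peaks in all 4 libraries, with scores of 20, 22, 26 and 17 for Cdh1 and 51, 61, 67 and 79 for Krt8. Epcam and Cldn3 had no listed peak at their ends or inside the gene in any library. Tjp1 had none at its outer ends but 7 to 11 peaks inside the gene. The gene-end peaks of Krt7 (15 at 50000 and 9 at 100000 cells), Cldn4 (10 and 11 at the same cell numbers), Cldn7 (8 at 25000 cells) and Pkp3 (8 at 25000 cells) had low scores, and that of Cldn7 lay nearer to the end of Elp5.

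Genes of differentiated mammary cells had few such peaks. Of 20 luminal and milk protein genes, 3 had a peak at a gene end in all 4 libraries, at the 0.4 percentile of random lists, and 13 had none in any library. The members with peaks were Mfge8, a milk fat globule protein gene, with scores of 37, 39, 43 and 31, Stat5a, a transcription factor gene of the prolactin pathway, with 30, 50, 26 and 48, and Areg, which encodes a ligand of the EGF receptor, with 15, 18, 20 and 26. Gata3, Foxa1 and Esr1, transcription factor genes of luminal cells, had no peak at their outer ends, but each had 1 to 3 peaks inside the gene in every library, with highest scores of 38 to 60 for Gata3, 8 to 13 for Foxa1 and 19 to 59 for Esr1. Counting peaks anywhere in the gene raised the number with a peak in all 4 libraries from 3 to 8, at the 10.1 percentile of random lists counted in the same way. At its ends, Xdh had a peak in 3 libraries (13, 15 and 11 from 50000 cells up), with 3 or 4 peaks in or beside the gene in every library. Gene-end peaks were found at Cited1 in 2 (12 at 50000 and 9 at 100000 cells) and at Csn3 in 1 (9 at 100000 cells). The Stat5b window contained a peak with a score of 48 at 100000 cells only, but that peak is the one at its neighbour Stat5a and overlapped a peak in all 3 other libraries.

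Of 20 basal and myoepithelial genes, 6 had a gene-end peak in all 4 libraries, at the 11.0 percentile, and 10 with peaks counted anywhere in the gene, at the 34.0 percentile. The integrin genes Itgb1 (31, 50, 40 and 57) and Itgb4 (26, 23, 41 and 19), the myosin kinase gene Mylk (21, 34, 33 and 19) and the growth factor receptor gene Egfr (24, 31, 22 and 17) were among them. The basal keratin genes Krt14 and Krt17 had no listed peak in or beside the gene, and Krt5 had only 1 peak with a score of 8 inside the gene, at 50000 cells. Myh11, Tagln, Lgr5 and Procr had gene-end peaks in some libraries with scores of 9 to 14, those of Tagln lying nearer to the end of Sidt2.

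Of 20 genes of epithelial-mesenchymal transition, 9 had a gene-end peak in all 4 libraries, at the 54.9 percentile, and 5 when only peaks at or above each list's median score were kept. Vim, which encodes the intermediate filament vimentin, scored 49, 49, 31 and 36, the repressor gene Snai1 27, 42, 41 and 40, S100a4 28, 38, 32 and 34, and Tcf4 17, 49, 29 and 48. Cdh11 and Twist1 had no listed peak in or beside the gene. Twist2 had none at its ends but 2 or 3 inside the gene in each library, with highest scores of 79, 117, 91 and 99. Zeb1 had a gene-end peak of 9 at 50000 and of 15 at 100000 cells. It had 1 to 3 peaks in or beside the gene in every library, with highest scores of 30, 15, 25 and 33.

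Signalling and immediate early genes had peaks in nearly all cases. Of 24 genes of TGF-beta signalling, a pathway known to act on these epithelial cells, 21 had a gene-end peak in all 4 libraries, at the 100 percentile of random lists. The feedback gene Skil scored 58, 66, 63 and 92, Id2 51, 89, 65 and 65, the matrix protein gene Ccn2 55, 56, 50 and 56, and the pseudoreceptor gene Bambi 59, 72, 36 and 61. Tgfb2 had no peak at its ends but 1 or 2 inside the gene in each library, and Tgfbr3 had a gene-end peak of 12 at 100000 cells. Ltbp1 had gene-end peaks of 8 at 25000 and of 12 at 100000 cells, and 16 to 23 peaks in or beside the gene in every library, with highest scores of 43, 67, 58 and 58. Of 18 AP-1 and immediate early genes, 17 had a peak in all 4 libraries, above 99.9% of random lists, with Myc, Atf3 (67, 62, 82 and 88), Ier2 and Fosl2 (43, 78, 68 and 71) at the top. The highest-scoring peak in the Ier2 window was at 84662401 to 84663150 on chromosome 8 at 50000 cells, with a score of 84, and at about 84663801 to 84664500, farther from the gene, in the other libraries, with 59, 64 and 67. Egr2 had no peak at its ends and 2 inside the gene in each library. Of 16 Hippo pathway genes, 14 had a peak in all 4 libraries, above 99.9% of random lists, and 9 when only peaks at or above each list's median score were kept. The target gene Ankrd1 scored 67, 96, 116 and 106, the phosphatase gene Ptpn14 80, 92, 67 and 99, Wwtr1, which encodes the co-activator TAZ, 67, 78, 65 and 89, and Amotl2 55, 60, 77 and 54. Tead2 had a peak in the 3 libraries from 50000 cells up (14, 10 and 16), and Amotl1 had peaks only inside the gene, 6 to 8 per library.

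Genes used by most cells had gene-end peaks in most cases. In all 4 libraries, a gene-end peak was found at 19 of 20 housekeeping genes, 18 of 22 cell cycle genes, 17 of 20 chromatin regulator genes and 14 of 16 stress response genes, each above 99.9% of random lists. The housekeeping gene without one, Ywhaz, had 3 to 6 peaks inside the gene in each library. Among housekeeping genes the ribosomal protein gene Rpl13a scored 60, 83, 84 and 93 while the peaks of 66, 70, 81 and 68 in the window of the elongation factor gene Eef2 lay nearer to the end of its neighbour Dapk3. Among cell cycle genes Ccna2, which encodes cyclin A2, scored 70, 86, 89 and 106 and E2f1 67, 79, 68 and 90. Plk1, Rb1 and Kdm1a had gene-end peaks in the 3 libraries from 50000 cells up and not at 25000 cells, with scores of 21, 17 and 28 for Plk1, 9, 8 and 15 for Rb1, and 9, 14 and 16 for Kdm1a. At 25000 cells Rb1 had 2 peaks inside the gene, with a highest score of 23, and Plk1 and Kdm1a had none. Cdkn2a had a gene-end peak of 8 at 75000 cells and Mta1 one of 8 at 25000 cells, both at the lowest score of the lists. Mta1 also had 2 to 5 peaks in or beside the gene in each library, with highest scores of 24, 28, 29 and 22. Cdkn1a and Rad21 had none at their outer ends but 3 or 4 peaks and 1 peak inside the gene. Among chromatin regulators Mbd3 scored 82, 122, 110 and 140, and the Polycomb genes Ezh2 and Suz12 scored 45, 61, 43 and 49, and 51, 61, 36 and 44. In the stress response list Dnajb1 scored 83, 85, 92 and 111 and Hspa5 66, 90, 55 and 103. Hspa1a, a near-identical neighbour of Hspa1b, had no listed peak, and Nqo1 had none at its ends.

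Markers of other cell types were mostly without a peak at a gene end. In all 4 libraries, gene-end peaks were found at 0 of 10 endothelial genes, 0 of 12 neuronal genes, 0 of 10 pluripotency genes, 1 of 10 fibroblast genes, 2 of 15 blood cell genes and 3 of 14 liver and muscle genes, at the 0.2, 0.035, 0.165, 1.44, 0.745 and 4.34 percentile of random lists. With peaks counted anywhere in the gene the numbers were 2, 3, 0, 3, 2 and 4. Among random lists counted in the same way these lay at the 1.585, 2.235, 0.03, 6.82, 0.06 and 2.905 percentile. In the same order, 6, 6, 8, 7, 11 and 6 genes had no listed peak in or beside the gene in any library. The fibroblast gene with a peak was the collagen gene Col1a1, with scores of 33, 30, 29 and 34, while Col1a2 and Col3a1 had no listed peak in or beside the gene. The blood cell genes were Spi1 (23, 18, 24 and 40) and the lysosomal gene Cd68 (14, 28, 23 and 27), while Ptprc, Cd3e and Cd3g had none. The liver genes were Apoa1 (27, 22, 35 and 30), the transcription factor gene Hnf4a (25, 31, 13 and 37) and Apob (12, 12, 9 and 11, the last from a peak farther inside the gene), while Alb had no gene-end peak and 1 inside the gene in each library. Pou5f1, Nanog, Sox2 and Kdr had no listed peak in or beside the gene. The endothelial gene Cdh5 had 1 peak inside the gene in each library, with scores of 47, 54, 50 and 57, and the neuronal gene Syt1 had 3 to 6. Members with gene-end peaks in some libraries had scores of 8 to 18, including Tubb3 in the 3 libraries up to 75000 cells (10, 10 and 12) and Ckm in the 3 from 50000 cells up (18, 10 and 8).

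**Figure D4:**
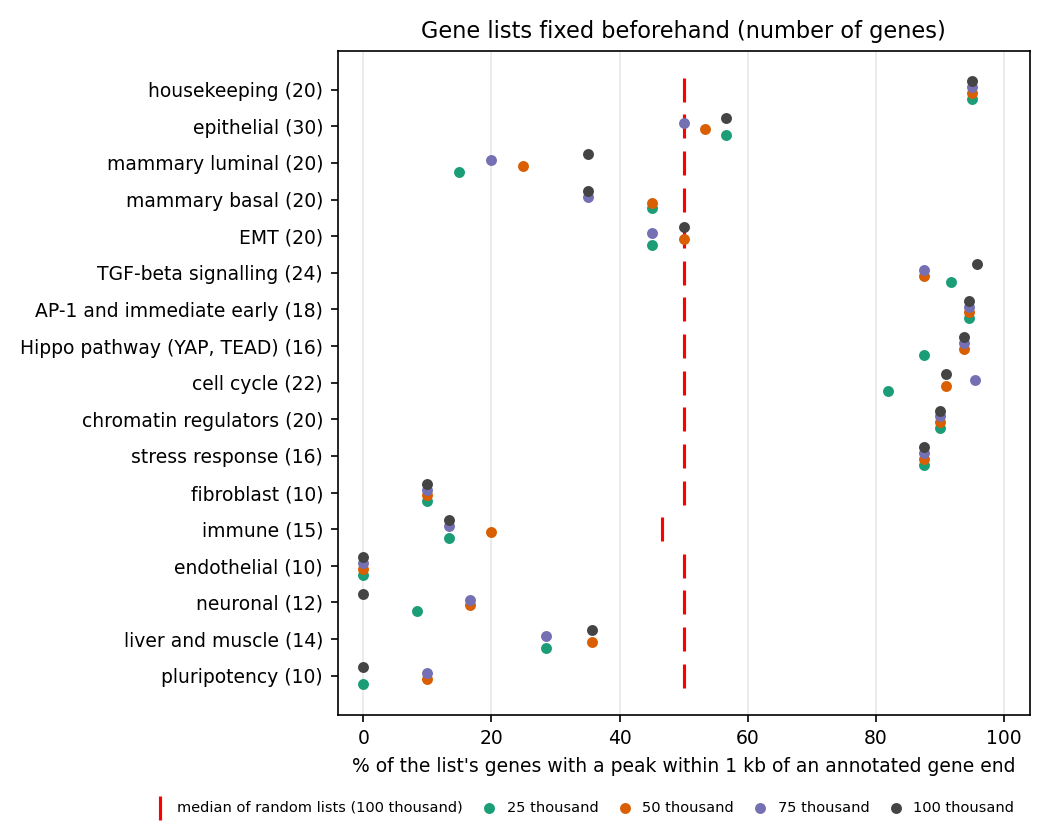
Share of each fixed list's genes (%) with a peak within 1 kb of an annotated gene end, 1 point per NMuMG library, with the number of genes in parentheses; red marks are the median of 10000 random lists for the 100000-cell library. Housekeeping, signalling, cell cycle, chromatin and stress lists lie above 80% in every library, and the 6 lists of other cell types lie below 40%.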

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

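Merging the overlapping peaks of a list, leaving out 61 to 64 Mb of chromosome 15 and counting peaks anywhere in a gene were chosen after seeing the data. Merging left the number of peaks within 1.5 times, and leaving out the chromosome 15 block left shares and regions within their 95% intervals. Restricting the lists to autosomes kept both the numbers and the shares within those limits. No result rests on a test. Keeping only peaks at or above each list's median score left 19905, 22447, 22085 and 23540 peaks from 25000 to 100000 cells. The share of peaks found in all 3 other libraries then was 75.6%, 66.8%, 68.0% and 63.8%. All 4 lists were cut in this way, so a match below the median score of another list no longer counted. Against the full lists, 73.2% to 89.2% of the peaks with scores from 15 to 24 were found in all 3 other libraries. With all peaks, the share found in all 3 other libraries was 65.9%, 58.6%, 61.8% and 56.2% with a reciprocal overlap of 50%. It was 64.8%, 57.5%, 60.9% and 55.2% for peaks resized to 200 bp. Both are stricter definitions of overlap. With equal list lengths it was 68.8% at 25000, 66.6% at 50000 and 66.2% at 100000 cells. Regions found in every library made up 49.9% at or above the median score, 47.4% with equal list lengths and 41.8% with resized peaks; leaving out each library in turn gave 52.5% to 54.0%, where fewer libraries have to agree. The share of peaks at gene ends was 27.2%, 25.4%, 26.6% and 25.4% within 500 bp, 43.8%, 41.9%, 42.8% and 41.7% within 2.5 kb, 28.2%, 26.3%, 27.6% and 26.2% for protein-coding genes only, and 41.6%, 40.8%, 41.0% and 40.6% at or above the median score. With equal list lengths it was 32.3% at 50000, 33.1% at 75000 and 33.0% at 100000 cells. The larger share among higher-scoring peaks was found in all 4 libraries, and its cause was not tested.

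The number of genes with a gene-end peak in all 4 libraries stayed within 1.5 times for all 17 lists with a window of 500 bp and with equal list lengths. At or above the median score it was 5 for epithelial-mesenchymal transition, 9 for the Hippo pathway, 1 for blood cells and 1 for liver and muscle. Counted anywhere in the gene, where a wider stretch was searched, it was 8 for luminal, 10 for basal, 3 for fibroblast, 2 for endothelial and 3 for neuronal genes. The percentile among random lists counted in the same way rose from 0.4 to 10.1 for luminal and from 11.0 to 34.0 for basal genes. It rose for the fibroblast, endothelial and neuronal lists as well, and fell for the blood cell, pluripotency and liver and muscle lists. The random lists were not matched on gene length, so whether the wider stretch alone accounts for the higher numbers stays open. The motif count was not run, and neither were its 2 alternatives, a narrower window and equal list lengths. No paired analysis was possible because each cell number has a single library. Unknown depth limits every comparison of list lengths.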

Other observations

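The gene families described here were chosen after the data were examined, and so were all tests below except those on the score and on the list length of peaks found in all other libraries. Gene-end peaks were counted in families of related genes, without a test of enrichment. Over all protein-coding genes, 43.9% had such a peak in all 4 libraries. Of 1110 olfactory receptor genes, 0 had a peak in all 4 libraries (95% interval up to 0.332%), and 1100 had none in any library. Among 353 vomeronasal receptor genes 1 had such a peak, and among 71 defensin and 26 kallikrein genes there were 0. Of 71 cytochrome P450 genes of the Cyp2, Cyp3 and Cyp4 families, 4 had one, including Cyp2s1 and Cyp4f13, and 61 had none in any library. By contrast, 67 of 76 cytosolic ribosomal protein genes (88.2%, 78.7 to 94.4), 64 of 77 mitochondrial ribosomal protein genes and 32 of 39 proteasome subunit genes had a peak in all 4 libraries. Of 367 zinc finger genes named Zfp, 214 had one (58.3%, 53.1 to 63.4), nearer to the 43.9% of all protein-coding genes.

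Of 49 keratin genes, 6 had a gene-end peak in all 4 libraries, namely Krt8, Krt18, Krt19, Krt20, Krt10 and Krt80. Of 23 claudin genes, which encode tight junction proteins, the 2 with such a peak were Cldn6 and Cldn12. Of 21 integrin genes, 11 had one (52.4%, 29.8 to 74.3), among them Itga1, Itga2, Itga3, Itga6, Itgb1 and Itgb4. The interval for integrins includes the 43.9% of all protein-coding genes. In the Hoxc and Hoxd clusters, which hold regulators of position along the body axis, none of the 9 genes each had a gene-end peak in any library.

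Peaks of a single library made up 6.72% to 11.0% of the lists. In every library at least 97.5% of them scored below the median of their list, in line with weak sites near the score threshold that pass it in 1 list and miss it in another. The share of single-library peaks differed by 4.33 percentage points between libraries with full lists and by 0.352 with equal numbers of highest-scoring peaks, but this decides nothing, since shortening the longer lists removes their lowest-scoring peaks, where single-library peaks lie. For the share found in all 3 other libraries, the gap fell from 11.3 to 2.54 percentage points, which decides nothing either, since equal lengths divide nearly the same set of shared peaks by the same number. Whether list length accounts for the differences between libraries, and what set it, stays open with 1 library per cell number, and no biological explanation was tested.

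The dense block of peaks on chromosome 15 from 61 to 64 Mb, around Myc and Pvt1, holds more peaks per Mb than most of the genome in each library. Peaks piled up in a few places of the block would leave most of its 100 kb bins sparse, but in every library at least 70% of these bins held more peaks than the 95th percentile of all bins; repeated sequences spread through the block are not excluded by this, and stay open without the genome sequence. High gene density is also argued against, since the block averages 10.7 genes per Mb, at the 0 percentile of the other 25 windows in the top 1% by peak number, which hold at least 35. A candidate explanation that stays open is that the cells carry more copies of this block, which would lift many weak sites over the threshold; peaks of a single library were enriched in it over the genome at least 2.22 times as strongly as peaks found in all 3 other libraries, and 59.5% to 69.6% of its peaks scored below the list median. A broad stretch of open chromatin over the block would give weak peaks as well, the number of copies was not measured, and the design has no group that tests a biological explanation.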
